A study of Callithrix jacchus with 5 samples.

How the data were processed

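RNA sequencing counts per gene were analysed for 5 libraries of common marmoset cells: 1 of fibroblasts, 3 of ES cells from separately named lines and 1 of iPS cells. Total RNA was extracted with a Qiagen RNeasy Mini kit and libraries followed standard Illumina protocols, per the labels' protocols. The titles carry P numbers of 1 for the fibroblasts and 63, 17 and 45 for ES lines 1, 2 and 3, which were not used as a covariate. The authors deposited whole-number read counts per gene, not normalized, in a table of the series and in a file per library, and the counts were identical in both. Trim Galore 0.4.0, STAR 2.5.3a and featureCounts 1.5.2 are named in the submitters' processing notes, which give no role or order. The genome build, and the settings for strand, multi-mapping reads and overlapping genes, are not given in the sources used here. Genes with near-identical copies, such as POU5F1 with its pseudogenes or members of the NLRP and HOX families, and genes that overlap a neighbour on either strand, may therefore share reads, and their values are uncertain to that extent. The gene model of POU5F1 in the files is also far longer than the gene is known to be. Coordinates are those of the files, 1-based.

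The count table holds 30811 gene identifiers, of which 12660 (41.1%) matched a symbol in the gene name table used here. The other identifiers entered every test but are named only by identifier. Of 577 entries in 27 gene lists, 382 matched an identifier, so lists are described by their measured members. THY1, which the rule for named genes asks for, has no match and is not analysed here. A RefSeq gene table on another assembly was not used.

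Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept with filterByExpr on the 3 groups, which left 17462, and libraries were scaled with TMM factors (0.813 for the fibroblast library, 1.06, 1.05 and 1.07 for ES lines 1 to 3, and 1.03 for the iPS library). All 5 libraries entered 1 fit (estimateDisp, glmQLFit) with the groups as levels, and glmQLFTest compared the fibroblast library with the ES lines and the iPS library with the ES lines. Only the ES lines are replicated, so the lone libraries are assumed to vary like an ES line, and the p-values measure the spread between these 3 lines, which differ in origin and in P number. The common biological coefficient of variation was 0.458. P-values were adjusted by Benjamini-Hochberg over all genes tested and called under 0.05. CPM values printed are counts scaled to a common TMM-adjusted library total. Log2 CPM used a prior count of 2. Where a library or group had no count, the fold is a lower bound against 3 counts, over the library or over the 3 ES libraries together. Intervals for single libraries are 95% exact Poisson intervals. Intervals and floors cover counting error only, since reads were counted without molecular identifiers.

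Gene lists were tested with camera at a preset correlation of 0.01 over the 25 lists with at least 3 genes tested, with Benjamini-Hochberg adjustment. With an estimated correlation no list passed in either comparison. The iPS and fibroblast libraries were compared without a test, by log2 ratios and by the percentile of a list's median among 10000 random lists of the same size matched on mean expression. The yardstick fits set each ES line, or the iPS library, against the other 2 ES lines. The position of the iPS library is the share of called genes whose log2 CPM lies nearer the ES mean than the fibroblast value. No batch is given in the labels.

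Genes named in the text follow a rule: the 10 named genes with the largest fold change in each direction among those that passed with at least 5 CPM in the higher group, up to 4 called members of each list with the smallest adjusted p, and POU5F1, NANOG, SOX2, LIN28A, KLF4, MYC, CDH1, EPCAM, COL1A1 and VIM whatever their result. Some genes the rule gives are left out where they repeat a family already shown, and some others are not reported. Other list members named (such as FBLN1, PDGFRB and the members that passed on a list alone), ENSCJAG00000018981, and COL3A1 and COL5A2 beside the position of the iPS library, were chosen after their values were seen. The groups, tests, gene lists, rule and first set of alternatives were fixed before the data were examined.

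The steps were tested on simulated counts drawn from the means of the ES lines and the totals of all libraries, with 200 genes changed. Every library was given the same spread per gene, and only genes above a mean of 1 CPM in the ES lines were changed. The shares recovered therefore do not cover genes silent in the ES lines. For the fibroblast comparison (16881 genes in the fit) 17% of 4-fold and 76% of 16-fold changes were recovered, with 11 false calls. For the iPS comparison (16942 genes) 18% and 75% were recovered, with 2 false calls. The alternatives tried were RLE and upper-quartile factors, total counts alone, no low-count filter, a stricter filter of mean CPM 1, DESeq2, limma voom, robust edgeR, fits on the 2 groups compared, glmTreat against a 2-fold change, leaving out each ES line, and fry or an estimated correlation for lists. Thinning to the iPS total of 5746449 counts, leaving out chromosomes 9 and 15, and the simulated overlap at the sizes of the real lists were added after seeing the data.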

Results

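Transcript abundance was measured by RNA sequencing in cultured cells of the common marmoset (Callithrix jacchus), a small New World monkey. The 5 libraries fall into 3 groups: 1 library of fibroblasts, 3 libraries of embryonic stem (ES) cells, each from a line of its own, and 1 library of induced pluripotent stem (iPS) cells. Fibroblasts are connective tissue cells. The iPS cells were obtained from fibroblasts by delivering reprogramming factors as RNA, per the series title, and the labels do not say whether their parent cells were those sequenced here. Total counts over genes were 58601185 in the fibroblast library, 46523012, 34111715 and 40825547 in ES lines 1, 2 and 3, and 5746449 in the iPS library, which was therefore the shallowest. A count of 3 corresponded to 0.063 CPM (counts scaled to a common library total) in the fibroblast library, 0.061 to 0.083 CPM in the ES lines and 0.507 CPM in the iPS library. The fibroblast and iPS groups have no replicates, so every test borrowed its spread from the 3 ES lines, with 2 residual degrees of freedom. CPM values are scaled by TMM factors, ES values are means ± SD (n = 3), and fold changes are given on the log2 scale with their SE.

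The first comparison asked how the sequenced fibroblasts differ from established pluripotent lines. Most measured core pluripotency genes fell in the fibroblast library and most fibroblast and mesenchymal genes rose. POU5F1, the transcription factor also called OCT4, stood at 1.64 CPM in the fibroblast library and 1425 ± 301 CPM in the ES lines (log2 fold change -9.76 ± 0.63, adjusted p = 0.00121, edgeR quasi-likelihood test). NANOG, another core pluripotency factor, stood at 0.357 against 516 ± 49.9 CPM (log2 fold change -10.48 ± 0.59). SOX2 stood at 0.672 against 184 ± 52.5 CPM (-8.09 ± 0.67) and LIN28A, an RNA-binding protein that blocks let-7 maturation, at 0.126 against 411 ± 130 CPM (-11.63 ± 0.82). COL1A2, a chain of type I collagen, rose from 250 ± 19.05 CPM in the ES lines to 19646 CPM (log2 fold change 6.29 ± 0.29, adjusted p = 0.00092).

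In all, 1537 genes were higher and 1620 lower in the fibroblast library among 17462 tested, or 18.1% of them, and 1126 and 1522 of these were at least 4-fold apart. In the files' coordinates, whose genome build is not given in the sources used here, POU5F1 (ENSCJAG00000019789) spans 31626192 to 31822630 on chromosome 4. NANOG (ENSCJAG00000018999) spans 20166985 to 20173162 on chromosome 9, and COL1A2 (ENSCJAG00000013547) 53082558 to 53120083 on chromosome 8. The count fell to 1742 without ES line 1 and rose to 4550 without ES line 3. With total counts alone in place of TMM the split was 1066 higher and 2016 lower, and the median log2 fold change of all genes moved by -0.38, while limma voom tilted the split the other way, to 1674 higher and 1009 lower.

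Of 18 measured core pluripotency genes, 16 fell and 2, TEAD4 and FGFR1, did not pass (16 lower when adjusted over the list alone). Core pluripotency genes as a list had camera adjusted p = 1.4e-25, and adjusted p = 0.255 with an estimated correlation. SALL4, GDF3, LIN28B and TRIM71 were among those that fell, with log2 fold changes of -9.43, -10.62, -11.34 and -10.26. Of 10 genes associated with primed pluripotency, the state of the post-implantation epiblast, 6 fell, among them ZIC2 (-7.05 ± 0.55) (6 adjusted over the list alone). Primed state genes as a list had camera adjusted p = 4.98e-07, and adjusted p = 0.255 with an estimated correlation. Of 12 genes associated with the naive state, 4 fell: TFCP2L1, ESRRB, NR5A2 and PRDM14 (4 adjusted over the list alone). Naive state genes as a list had camera adjusted p = 0.0022, and adjusted p = 0.536 with an estimated correlation. TFCP2L1 and ESRRB had no count in the fibroblast library and were at least 57.8-fold and 31.8-fold lower there. The bound was 45.6-fold for TFCP2L1 without ES line 1 and 19.01-fold for ESRRB without ES line 3. Without ES line 1, 13 core genes and 2 naive genes fell, and GDF3, TFCP2L1 and ESRRB did not pass, while 8 naive genes fell without ES line 3. Among 8 reprogramming factors, POU5F1, SOX2, NANOG and LIN28A fell and GLIS1, a Krüppel-like zinc finger factor, rose (log2 fold change 3.96; 4 lower and 1 higher adjusted over the list alone). Reprogramming factors as a list had camera adjusted p = 3.25e-08, and adjusted p = 0.255 with an estimated correlation. KLF4 stood at 58.7 CPM in the fibroblast library and 153 ± 125 CPM in the ES lines (adjusted p = 0.477), and MYC at 157 against 249 ± 80.4 CPM (adjusted p = 0.338). KLF4 did pass as lower in fibroblasts without ES line 3.

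**Figure D1:**
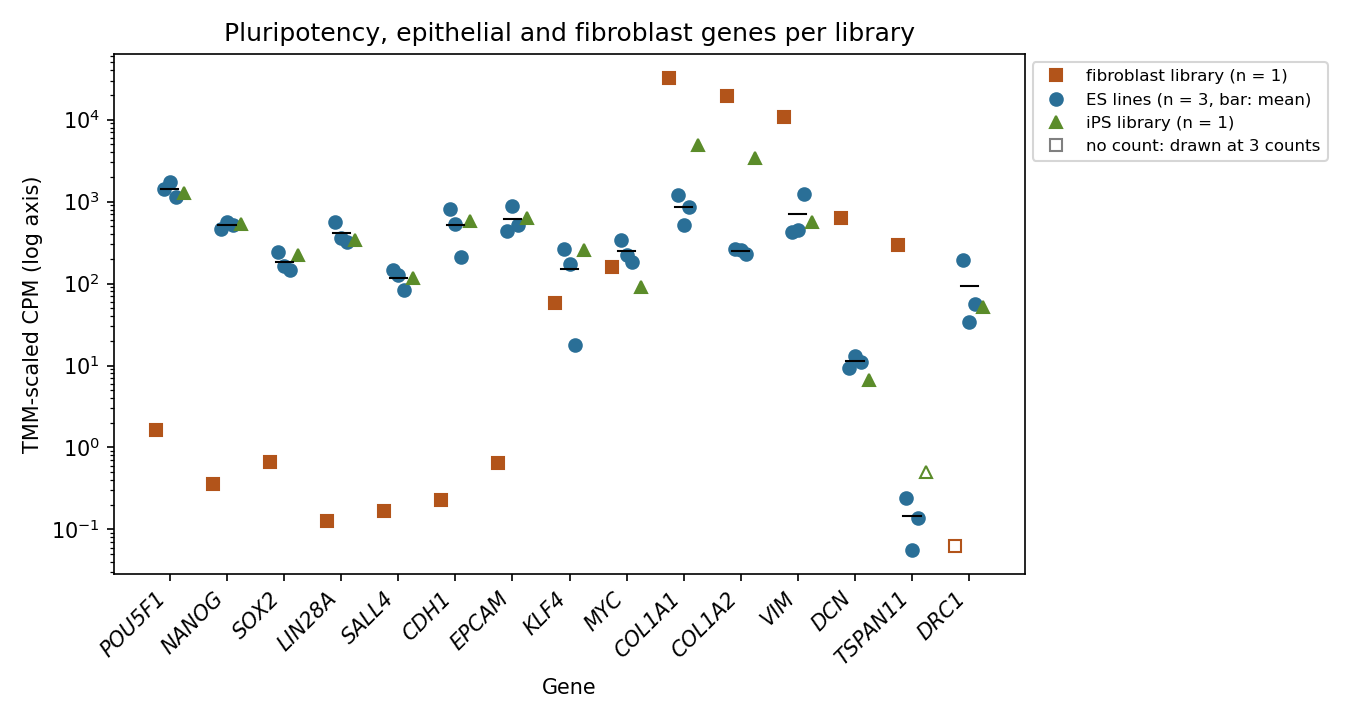
TMM-scaled CPM on a log axis for pluripotency, epithelial and fibroblast genes, with 1 point per library and a bar at the mean of the 3 ES lines. Open symbols mark a library with no count, drawn at 3 counts. POU5F1 lies at 1.64 CPM in the fibroblast library and 1286 CPM in the iPS library, and COL1A2 at 19646 and 3447 CPM.

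All 14 measured epithelial genes fell in the fibroblast library (14 adjusted over the list alone). Epithelial genes as a list had camera adjusted p = 2.08e-34, and adjusted p = 0.255 with an estimated correlation. CDH1, which encodes E-cadherin, stood at 0.231 CPM against 519 ± 302 CPM in the ES lines (log2 fold change -11.11 ± 1.27), and EPCAM at 0.651 against 616 ± 242 CPM (-9.88 ± 0.82). The tight junction genes CLDN4 and CLDN7 (-6.73 and -9.70) and the splicing regulator ESRP1 (-10.10) fell too. Of 30 fibroblast and mesenchymal genes, 28 rose, FBLN1 fell (-3.26) and PDGFRB did not pass (28 higher and 1 lower adjusted over the list alone). Fibroblast and mesenchymal genes as a list had camera adjusted p = 3.96e-36, and adjusted p = 0.117 with an estimated correlation. COL1A1 reached 32526 CPM against 862 ± 348 CPM (log2 fold change 5.24 ± 0.45), and the intermediate filament gene VIM 10815 against 706 ± 463 CPM (3.94 ± 0.58). COL6A2 stood at 6754 against 113 ± 24.3 CPM (5.91 ± 0.35) and the proteoglycan DCN at 636 against 11.2 ± 1.93 CPM (5.82 ± 0.34).

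The named genes with the largest rises were TSPAN11, WNT2, ABCA6, CPED1, CXCL14, NPR3, MXRA5, PRG4, ITGBL1 and COL12A1, with log2 fold changes from 10.88 down to 7.72. TSPAN11, a tetraspanin, stood at 292 CPM in the fibroblast library against 0.146 ± 0.094 CPM in the ES lines. WNT2, a secreted WNT ligand, stood at 370 against 0.306 ± 0.225 CPM, and MXRA5 at 2956 against 7.12 ± 1.11 CPM. Among the named genes with the largest falls by fitted fold change were DRC1, HTR3A, A2ML1, B3GNT7, TMPRSS13, SLC39A4, HPN, PTPN6 and OVOL2. None of these 9 had a count in the fibroblast library, so their order rests on the fit. Their bounds, 273-fold to 1489-fold, lie below the fitted 3176-fold of LIN28A and 2212-fold of CDH1, which had counts there. DRC1, a component of the axonemal dynein regulatory complex, was at least 1489-fold lower, or 714-fold without ES line 1. HTR3A, a serotonin-gated channel subunit, was at least 545-fold and OVOL2, a repressor of mesenchymal genes, at least 273-fold lower, each against a floor of 3 counts in that library. Without ES line 2 the bounds of HTR3A and OVOL2 were 495-fold and 197-fold.

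HOX genes, which set position along the body axis, rose in 8 of 22 cases, among them HOXC9 (log2 fold change 4.13 ± 0.68) and HOXC12 (6.85 ± 0.87) (12 adjusted over the list alone). HOX genes as a list had camera adjusted p = 2.56e-05, and adjusted p = 0.536 with an estimated correlation. Of 23 interferon response genes, 8 rose, including DTX3L (3.07 ± 0.44), while IRF7 (-3.87) and BST2 (-2.66) fell (13 higher and 2 lower adjusted over the list alone). Interferon response genes as a list had camera adjusted p = 5.17e-05, and adjusted p = 0.503 with an estimated correlation. Of 11 antigen presentation genes, 4 rose, including B2M, the light chain of class I molecules, at 402 against 84.9 ± 16.7 CPM, and TAPBP (3.29 ± 0.49) (6 adjusted over the list alone). Antigen presentation genes as a list had camera adjusted p = 0.00116, and adjusted p = 0.385 with an estimated correlation. Of 13 p53 and senescence genes, 2 rose, CDKN2B (2.51 ± 0.57) among them (2 adjusted over the list alone). Genes of p53 and senescence as a list had camera adjusted p = 0.00895, and adjusted p = 0.385 with an estimated correlation. CDKN2B did not pass without ES line 1 or with total counts alone. Without ES line 1, 2 HOX, 4 interferon response and 2 antigen presentation genes rose and IRF7 and BST2 did not pass, whereas 17, 17 and 7 rose without ES line 3. Of the p53 and senescence genes, 4 rose without ES line 2 or ES line 3 and 5 with DESeq2.

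Among early lineage genes, 7 of 13 endoderm genes fell and LGR5, a receptor for R-spondins, rose (4.90 ± 0.47; 8 lower and 1 higher adjusted over the list alone). Endoderm genes as a list had camera adjusted p = 0.00733, and adjusted p = 0.503 with an estimated correlation. FOXA2, GATA4 and HNF4A had no count in the fibroblast library against 8.43, 6.24 and 10.5 CPM on average in the ES lines, and were at least 134-fold, 99.0-fold and 167-fold lower. These bounds fell to 113-fold for FOXA2 without ES line 3, and to 70.4-fold for GATA4 and 122-fold for HNF4A without ES line 2. Of 7 mesoderm genes, KDR (-5.42 ± 0.48) and TBXT fell (3 adjusted over the list alone). Mesoderm genes as a list had camera adjusted p = 0.0219, and adjusted p = 0.385 with an estimated correlation. TBXT did not pass in 5 of 15 alternative fits, that without ES line 1 among them. Of 12 neural genes, 2 fell, NES among them, and PAX6 and MSX1 rose (3 lower and 4 higher adjusted over the list alone; camera adjusted p = 0.973), and NES, PAX6 and MSX1 did not pass without ES line 1. CYP19A1 passed alone among 12 trophoblast and amnion genes, at 0.63 CPM in the fibroblast library and without a count in the ES lines (0 adjusted over the list alone; camera adjusted p = 0.579). MAEL passed alone among 12 germ cell genes, at least 158-fold lower in the fibroblast library, or 95.5-fold without ES line 2 (0 adjusted over the list alone). Germ cell genes as a list had camera adjusted p = 0.0247, and adjusted p = 0.559 with an estimated correlation. Neither CYP19A1 nor MAEL passed without ES line 1, nor CYP19A1 with total counts alone, whereas without ES line 3 4 neural genes rose and 3 trophoblast and amnion and 5 germ cell genes fell. DESeq2 called 4 mesoderm, 3 trophoblast and amnion and 4 germ cell genes lower and 4 neural genes higher.

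Of 15 genes of DNA methylation, 5 fell and 1 rose. DNMT3B (-6.37 ± 1.04), DNMT3A (-2.79 ± 0.52) and TET1 (-3.67 ± 0.68) fell with HELLS and TRIM28. DNMT1, the maintenance methyltransferase, rose (2.59 ± 0.50) (6 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.179). DNMT1, HELLS and TRIM28 did not pass without ES line 1, nor TRIM28 without ES line 2. Of 17 imprinted genes, IGF2, PEG10, SGCE and IGF2R rose and PEG3, MEST, SNRPN and CDKN1C fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.667). SNRPN and CDKN1C did not pass without ES line 1, nor SNRPN without ES line 2. Among 30 cell cycle genes CCNE1 (-2.12 ± 0.41) and CDC25A (-1.69 ± 0.38) fell (1 adjusted over the list alone; camera adjusted p = 0.189), and CDC25A did not pass without ES line 1 or ES line 2. The cell cycle count was larger with upper-quartile factors (4 lower), total counts alone (5 lower) and DESeq2 (5 lower). In the 15 glycolysis genes PFKP rose and SLC2A1, a glucose transporter, fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.973), PFKP not passing without ES line 2, with upper-quartile factors or with total counts alone, and 2 rose and 3 fell without ES line 3. SDHA alone rose among 23 oxidative phosphorylation genes (1 adjusted over the list alone; camera adjusted p = 0.667), whose median log2 fold change of 0.14 turned to -0.25 with total counts alone. No apoptosis regulator of 14 passed with the edgeR quasi-likelihood test (0 adjusted over the list alone; 2 lower at an unadjusted p under 0.05, 2 lower with DESeq2 and 0 with limma voom; camera adjusted p = 0.97), though 1 fell in that test with upper-quartile factors, with total counts alone or without ES line 3.

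Markers of other cell types were examined in the same fit. Endothelial markers PECAM1 (-7.84 ± 0.60), KDR, VWF and ESAM fell and ENG rose (2.36) among 10 (5 lower and 1 higher adjusted over the list alone). Endothelial markers as a list had camera adjusted p = 0.00061, and adjusted p = 0.503 with an estimated correlation. ENG did not pass without ES line 1. Of 6 melanocyte and neural crest markers, 4 fell, among them PMEL, S100B and ERBB3 (4 adjusted over the list alone). Melanocyte and neural crest markers as a list had camera adjusted p = 0.000537, and adjusted p = 0.255 with an estimated correlation. S100B did not pass in 7 of the 13 alternative fits that gave it a value, those without ES line 1, 2 or 3 among them. The muscle markers CNN1 (4.25 ± 0.44), MYOD1, MYOG and TTN rose among 10 (5 adjusted over the list alone; camera adjusted p = 0.0428, adjusted p = 0.536 with an estimated correlation). Without ES line 1 only CNN1 of these 4 passed, and the list gave camera adjusted p = 0.156, or 0.114 without ES line 3. MYOD1 and MYOG stood at 1.28 and 2.1 CPM in the fibroblast library. RUNX1 rose among 3 blood markers (3.43 ± 0.57; 1 adjusted over the list alone; camera adjusted p = 0.573). Neither of 2 keratinocyte markers, TP63 and DSG3, passed over all genes (1 lower adjusted over the list alone and 1 lower with DESeq2), nor did EIF1AY, the only measured gene of the sex-linked list. The sign of the camera result differed from that of the median log2 fold change for the imprinted (-0.13) and blood marker (-0.88) lists, and the apoptosis list had a median of 0.11 and a mean of -0.18.

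The second comparison asked how far the reprogrammed cells differ from ES lines. The pluripotency and epithelial genes of the iPS library did not pass the test against the ES lines. POU5F1 stood at 1286 CPM against 1425 ± 301 CPM (log2 fold change -0.15 ± 0.36, adjusted p = 0.937) and NANOG at 539 against 516 ± 49.9 CPM (0.06 ± 0.32, adjusted p = 0.975). SOX2 stood at 221 against 184 ± 52.5 CPM (0.27 ± 0.40) and LIN28A at 339 against 411 ± 130 CPM (-0.28 ± 0.42). Among the genes that rose, COL1A2 reached 3447 CPM against 250 ± 19.05 CPM (3.78 ± 0.27, adjusted p = 0.0205). COL12A1, a fibril-associated collagen, reached 322 against 15.5 ± 1.10 CPM (4.37 ± 0.29, adjusted p = 0.0205), and PRRX1, a mesenchymal homeobox factor, 389 against 28.7 ± 5.89 CPM (3.76 ± 0.34, adjusted p = 0.0349). CXCL12, a chemokine made by stromal cells, rose most among named genes, from 10.2 ± 4.33 to 388 CPM (5.25 ± 0.50, adjusted p = 0.0366).

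In all, 19 genes were higher and 0 lower in the iPS library by the edgeR quasi-likelihood test. At an unadjusted p under 0.05 there were 971 higher and 547 lower, and other tools gave 351 higher and 65 lower with DESeq2, and 5 higher and 0 lower with limma voom. Among the 19, 10 have a symbol. Besides the 4 above these were TBX15 (4.99 ± 0.44), PORCN, an acyltransferase that lipidates WNT ligands (4.39 ± 0.40), NFIX (4.31 ± 0.44), the kinase RPS6KB1 (3.93 ± 0.30), PCSK5 (3.89 ± 0.40) and the calcineurin subunit PPP3CA (3.31 ± 0.32). The largest difference of all was in ENSCJAG00000018981, which has no symbol here and lies at 33664555 to 33671246 on chromosome 20, at 431 CPM in the iPS library against 2.98 ± 1.18 CPM. No gene passed without ES line 1, when 863 higher and 560 lower genes had an unadjusted p under 0.05, and 41 and 268 passed without ES line 2 and ES line 3. With every library thinned to the iPS total 91 genes passed, all 19 among them.

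**Figure D2:**
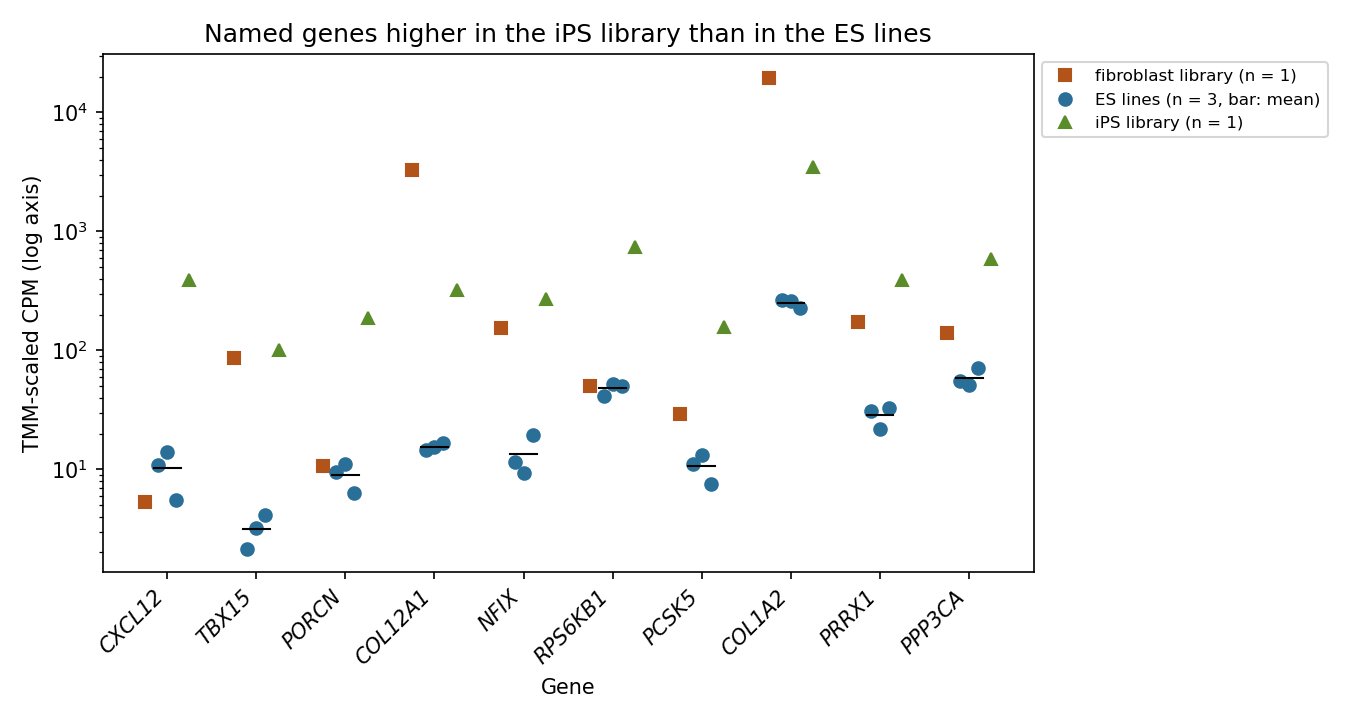
TMM-scaled CPM on a log axis for the 10 named genes that were higher in the iPS library than in the ES lines, with 1 point per library and a bar at the mean of the 3 ES lines. CXCL12 stands at 388 CPM in the iPS library and 5.36 CPM in the fibroblast library, and COL12A1 at 322 and 3264 CPM.

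Of the 19 genes, 10 were also higher and 1 lower in the fibroblast library than in the ES lines. Independent lists would share 1.67 genes. In 20 simulated draws without any change, the 1537 and 19 higher genes of smallest p in each comparison shared 10.05 genes on average (5 to 15), since both comparisons use the same ES lines. These draws hold no real change, whereas the shared genes include large fibroblast differences, such as COL12A1 (log2 fold change 7.72) and COL1A2 (6.29). The simulated overlap is therefore no baseline for the 10 shared genes, nor is the value for independent lists. Whether 10 is more than the shared ES lines would give was not decided. Called genes were too few in these draws to serve as a measure (1 and 1.25 on average, sharing 0.1). In the iPS library 13 of the 19 had a CPM more than 2-fold above that of the fibroblast library, among them CXCL12, PORCN and RPS6KB1 (732 against 50.1 CPM).

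Over the 30 fibroblast and mesenchymal genes, COL1A2 and PRRX1 passed the edgeR test over all genes (0 without ES line 1 and 8 without ES line 3; 7 higher and 3 lower with DESeq2 and 1 higher with limma voom) and 9 higher and 3 lower did when adjusted over the list alone. The median log2 fold change was 0.01 and the mean 0.48, with camera adjusted p = 0.00433, adjusted p = 0.931 with an estimated correlation, and camera adjusted p = 0.107 without ES line 1. The members higher on the list alone also held ZEB2 (3.33), COL3A1 (3.95), COL5A2 (3.17), COL1A1 (2.51), FAP (4.53), TWIST2 (2.27) and ZEB1 (2.36), and those lower were TGFBI (-3.64), CD44 (-2.18) and TAGLN (-2.93). The median turned to -0.03 with total counts alone. VIM, at 560 against 706 ± 463 CPM, did not pass. HOX genes were lower as a list (camera adjusted p = 6.63e-08, adjusted p = 0.931 with an estimated correlation). The edgeR test called 0 of 22 over all genes and 6 adjusted over the list alone, against 10 lower at an unadjusted p under 0.05, 2 lower with DESeq2 and 0 with limma voom. Of the 22, 14 had no count in the iPS library, and the list's median was -1.87 with such genes at the bound their floor allows. Endoderm genes were also lower as a list (camera adjusted p = 0.00598, adjusted p = 0.931 with an estimated correlation, median -1.51), with 0 of 13 over all genes and LGR5 adjusted over the list alone by the edgeR test. DESeq2 and the fit without ES line 3 each called 1 endoderm gene lower over all genes.

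None of the 18 core pluripotency, 14 epithelial or 10 primed genes passed with the edgeR quasi-likelihood test, adjusted over all genes or adjusted over the list alone. None of them had an unadjusted p under 0.05 or passed with DESeq2 or limma voom. Camera adjusted p values were 0.844, 0.688 and 0.698. Adjusted over the list alone, ARGFX (5.23) passed among the naive genes, PAX3 (6.47) among the neural and TFAP2A (4.97) among the trophoblast and amnion genes. So did RUNX1 (2.54) among the blood and MYH11 (2.54) among the muscle markers, each higher and none over all genes by the edgeR test. DESeq2 called 1 gene higher over all genes in each of these 5 lists, and edgeR 1 neural and 1 trophoblast and amnion gene higher with upper-quartile factors, without ES line 2 or without ES line 3. Without ES line 3 it also called 1 blood marker higher and 1 trophoblast and amnion gene lower. In the other lists (mesoderm, germ cell, interferon response, antigen presentation, cell cycle, p53 and senescence, glycolysis, oxidative phosphorylation, imprinted, DNA methylation, apoptosis, endothelial, melanocyte and neural crest, keratinocyte, sex-linked and reprogramming factors) no gene passed the edgeR test over all genes or adjusted over the list alone. DESeq2 called 1 imprinted and 1 DNA methylation gene lower. KLF4 at 255 against 153 ± 125 CPM and MYC at 90.1 against 249 ± 80.4 CPM did not pass (adjusted p = 0.882 and 0.419). Without ES line 2 the naive, germ cell and interferon response lists passed camera (adjusted p = 0.00125, 0.000247 and 0.00685), and without ES line 1 the naive, interferon response and endothelial lists did (adjusted p = 0.045 each). For muscle, melanocyte and neural crest, oxidative phosphorylation and reprogramming lists the camera sign was positive while the median was -0.44, -0.04, -0.07 and -0.04.

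The ES lines themselves served as a yardstick for these counts: each ES line, and then the iPS library, was set against the other 2 ES lines. In this comparison ES line 1 and the iPS library each gave 0 genes by edgeR's quasi-likelihood test, with 1 residual degree of freedom. ES line 2 gave 7 and the iPS library 29, and ES line 3 gave 96 and the iPS library 266. For the pair without ES line 1, 916 genes for that line and 1450 for the iPS library had an unadjusted p under 0.05, and DESeq2 called 69 and 446. DESeq2 called 46 and 317 genes for the pair without ES line 2, and 456 and 426 for the pair without ES line 3, where the order turned.

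The position of the iPS library was then described over the 3157 genes that separated fibroblasts from ES lines. Its level lay nearer the ES mean than the fibroblast value in 2956 of them, or 93.6%, and inside the range of the 3 ES lines in 38.8%. Genes lower in fibroblasts lay nearer ES in 96.98% of cases and genes higher in fibroblasts in 90.1%. ES lines held out in turn lay nearer the other 2 ES lines in 97.6%, 97.7% and 87.3% of the genes called without them. The iPS library did so in 93.6%, 92.9% and 92.5% of the same genes. Held-out ES lines 1, 2 and 3 lay inside the range of the other 2 in 24.6%, 37.2% and 23.7% of these genes, and the iPS library in 20.7%, 29.2% and 28.4%. Without any choice of genes, a library drawn like the ES lines would lie inside the range of 3 in 50% and of 2 in 33.3%. The 38.8% over 3 lines is thus not comparable with the shares over 2. COL3A1 (1684 CPM in the iPS library, 109 in the ES lines and 7339 in fibroblasts) and COL5A2 (810, 89.9 and 3174 CPM) were among the genes nearer the fibroblast value on the log scale. The choice of genes by the fibroblast value biases this share towards ES for any gene called by chance.

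Across 17462 genes, the Pearson correlation of log2 CPM was 0.941 to 0.958 between ES lines and 0.896 to 0.924 between the iPS library and the ES lines. It was 0.796 to 0.836 between the fibroblast library and the ES lines, and 0.76 between the fibroblast and iPS libraries. Spearman correlations were 0.953 to 0.965, 0.924 to 0.947, 0.816 to 0.848 and 0.796. Average-linkage clustering joined ES lines 1 and 2 first, then ES line 3, then the iPS library and last the fibroblast library. After thinning to the iPS total the iPS library correlated at 0.88 to 0.917 with the ES lines, and the ES lines at 0.923 to 0.943 with each other. These are correlations across genes, which are not independent replicates.

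The iPS and fibroblast libraries were compared directly to describe what separates the reprogrammed cells from fibroblasts, with no test, since each group has 1 library and the difference has no replicate check. Among 12174 genes at 5 CPM or more in either library, 1544 were at least 4-fold higher in the iPS library and 1524 at least 4-fold higher in the fibroblast library. With a minimum of 1 CPM these were 2761 and 1807, so the balance of the split depends on this choice. The named genes with the largest ratios towards iPS, at a prior count of 2, were NLRP9, NLRP7, LIN28B, GDF3, CDH1, LIN28A, PYY, A2ML1, NANOG and DDX43. NLRP7, a gene of oocytes and early embryos, stood at 730 CPM (95% Poisson interval 708 to 752) in the iPS library and 0.168 CPM (0.073 to 0.331) in the fibroblast library. The largest ratios towards fibroblasts at that prior count were in TSPAN11, ADAMTSL3, LRRC15, CCN4, PRG4, MXRA5, WNT2, EDNRB, DOCK10 and LGR5. Of these, only MXRA5, WNT2 and LGR5 had a count in the iPS library (16, 2 and 1), so the order of the others is set by the prior count. Against a floor of 3 counts TSPAN11 was at least 575-fold and DOCK10 at least 77.2-fold higher in fibroblasts, less than the 1093-fold of MXRA5. MXRA5 stood at 2.7 CPM (1.55 to 4.39) in the iPS library and 2956 CPM (2941 to 2972) in the fibroblast library. COL1A1 at 4922 against 32526 CPM and VIM at 560 against 10815 CPM were lower in the iPS library, and KLF4 at 255 against 58.7 CPM higher.

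Among gene lists, the median log2 ratio of iPS over fibroblast was 8.76 for core pluripotency and 8.44 for epithelial genes, above all 10000 random lists matched on size and expression, and so were the primed (4.18), naive (5.30) and reprogramming (5.18) lists. It was -3.62 for fibroblast and mesenchymal genes, -6.54 for HOX genes, -2.92 for interferon response and -2.40 for antigen presentation genes, below all 10000. Since 14 of the 22 HOX and 3 of the 23 interferon response genes had no count in the iPS library, these medians rest in part on the prior count, and were -4.28 and -2.61 with libraries without a count set to 3 counts. The p53 and senescence list lay at percentile 1.85 (median -1.11), and the endoderm, germ cell, DNA methylation, endothelial, and melanocyte and neural crest lists at percentiles 99.3, 99.7, 99.9, 98.3 and 99.2 (medians 3.86, 3.53, 0.85, 3.18 and 2.97). The neural, mesoderm, trophoblast and amnion, cell cycle, glycolysis, oxidative phosphorylation, imprinted, apoptosis, blood and muscle lists lay between percentiles 12.4 and 92.5. Of these, the neural and the trophoblast and amnion lists had 4 and 5 of 12 genes without a count in the iPS library, and their medians of 0 and -0.38 moved to 2.51 and 1.30 with libraries without a count set to 3 counts, so neither direction is secure.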

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

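No paired analysis was possible because the fibroblast and iPS groups have 1 library each. The iPS depth limits that library to about 0.507 CPM, and in simulated iPS counts 18% of 4-fold changes were recovered. Thinning, and leaving out chromosomes 9 and 15, were chosen after seeing the data, and the cause of the differences below was not tested. In place of the 3157 genes between fibroblasts and ES lines, DESeq2 gave 4736 and glmTreat 2022, and leaving out an ES line gave 1742 (line 1) to 4550 (line 3), with fewer libraries behind the spread. No gene of the 3157 changed sign in any fit that tested it. In place of the 19 genes between iPS and ES, no low-count filter gave 204, DESeq2 416, limma voom 5, glmTreat 5, thinning 91, and leaving out an ES line 0 (line 1) to 268 (line 3). RLE and upper-quartile factors, total counts alone, robust edgeR, the stricter filter, 2-group fits and leaving out chromosomes 9 and 15 stayed within 1.5 times of both counts. The median log2 fold change of all genes in the fibroblast comparison moved by -0.26 with upper-quartile factors and -0.38 with total counts alone. Of 96 named genes called between fibroblasts and ES lines, 69 passed in every fit that gave a value, and 21 lost their call without ES line 1. All 10 named iPS genes did so too. Lists past adjusted p 0.05 went from 16 (fibroblast) and 3 (iPS) to 0 and 0 with an estimated correlation and to 2 and 0 with fry, and leaving out an ES line gave 3 to 6 for iPS. The share of genes nearer ES was 92.5% to 94.2% across the fits without 1 ES line. The mean iPS to ES correlation less that between ES lines, -0.036, was -0.023 with no filter, -0.0505 with a prior count of 0.5 and -0.112 over the 1000 most variable genes. In the yardstick DESeq2 gave 69, 46 and 456 genes for ES lines 1, 2 and 3 and 446, 317 and 426 for the iPS library against the same pairs, and ES line 3 thinned gave 42.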

Other observations

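The test of the iPS library against the ES lines and the gene lists were planned, and the other tests in this part, those of chromosomes, depth, carry-over, kept expression and single-exon models, were chosen after the patterns had been seen. A few genes known from germ cells and the early embryo, chosen after their values were seen, are given here; none passed the test of the iPS library against the ES lines, nor did any of the 12 listed germ cell genes. DPPA5, a marker of early embryonic and germ cells, stood at 43.9, 189 and 0.274 CPM in ES lines 1, 2 and 3 and at 200 CPM in the iPS library. DDX4, an RNA helicase of germ cells, stood at 1.10, 12.7 and 0.046 CPM and at 26.5 CPM, PIWIL1 at 24.9, 46.1 and 0.823 CPM and at 52.1 CPM, and the meiotic gene SYCP1 at 9.996, 27.1 and 0.412 CPM and at 55.4 CPM. KLF4 was likewise lowest in ES line 3, at 265, 175 and 18.0 CPM, with 255 CPM in the iPS library. TBXT, a gene of the primitive streak, stood at 10.97, 115 and 9.31 CPM in the ES lines and 38.7 CPM in the iPS library.

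The first pattern weighed is the set of 19 genes higher in the iPS library than in the ES lines. Lower depth was not decided by thinning. All 19 passed with a median log2 fold change of 4.32 after every library was thinned to the iPS total, so the calls held at equal totals. But thinning keeps the expected ratios of such genes and leaves the iPS library as it was. An error of that shallow library would therefore remain. Counting error alone is argued against for the 19 genes. ENSCJAG00000019128, lowest of them in the iPS library, had a lower 95% Poisson limit of 29.6 CPM there against 0.951 ± 0.305 CPM in the ES lines. For ENSCJAG00000005322, which had the smallest fold change, the limit was 1130 against 119 ± 23.2 CPM. Fibroblasts like those sequenced, carried over into the iPS culture, were argued against only narrowly by the fibroblast and mesenchymal list. At the smallest share any of these genes needs (9.43%, from COL12A1), 15 of 28 fibroblast genes lay under 50% of the level that share would give. The cut-off was more than 50% of these genes, and FBN1 (96.5 against 202 CPM needed) and TIMP1 (26.2 against 55.3 CPM) lay just under their limit. COL6A2 (115 against 714 CPM), VIM (560 against 1409 CPM), ACTA2 and TAGLN lay further below. In contrast, COL1A1, COL3A1 and COL5A2 implied shares of 12.8%, 21.8% and 23.3%. A first test on the median share was undecided (0.053%, 95% bootstrap interval -1.42 to 10.99, against 16.5% for COL1A2). Of the 10 named genes with the largest rises in fibroblasts, TSPAN11, ABCA6 and PRG4 had no count in the iPS library (292, 37.0 and 69.5 CPM in fibroblasts). WNT2, CPED1, CXCL14, NPR3, MXRA5 and ITGBL1 stood at 0.338 to 5.58 CPM there, against 117 to 2956 CPM in fibroblasts. Only COL12A1, which set the share, went the other way. These levels argue against cells like those sequenced at a share of 9.43%. Fibroblast expression kept at the level of the sequenced cells was not decided for the set. Of the 19 genes, 13 lay more than 2-fold above that level in the iPS library. They hold genes not called higher in fibroblasts, such as CXCL12, PORCN and RPS6KB1, which this explanation does not concern. Of the 10 called higher in fibroblasts, PRRX1 (389 against 174 CPM), PPP3CA (584 against 140 CPM), ENSCJAG00000021367 and ENSCJAG00000005322 lay over 2-fold above it. The other 6 were mixed. COL12A1 (322 against 3264 CPM) and COL1A2 (3447 against 19646 CPM) lay well below it, so partly kept expression stays open for both. NFIX (268 against 154 CPM), TBX15 (101 against 86.2 CPM) and ENSCJAG00000019128 (34.1 against 22.1 CPM) lay above it. ENSCJAG00000021562 (57.5 against 66.9 CPM) lay close to it. Also open are fibroblasts of another kind, differentiating cells in the culture and a parent line unlike the one sequenced. Loosely matched reads, or reads from another species such as a feeder layer, which the labels do not mention, may also land on single-exon models, and these stood 0.24 (log2, 95% bootstrap interval 0.08 to 0.38) above other genes of like expression in the iPS library, against -0.27, 0.12 and 0.12 in the ES lines. The intervals of the iPS library and of ES lines 2 and 3 overlap, so this source cannot be told apart from the open ones.

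The second pattern weighed is a shift of whole chromosomes in ES line 3. Over 9950 genes at 10 CPM or more, its genes on chromosomes 9 and 15 stood 0.35 and 0.37 (log2 medians of 544 and 406 genes) above the other 2 ES lines, beyond all random gene sets of those sizes, and 0.35 and 0.33 above the iPS library. Lying beyond all random sets is not particular to them. Chromosomes 2 (0.10), 20 (-0.15) and 22 (-0.26) in ES line 3 did so too. So did chromosomes 3 (-0.13) and 11 (0.11) in ES line 2 and 14 (0.15) in ES line 1. A trend with gene length or expression is argued against, since the smaller of the medians of chromosomes 9 and 15 was still 0.35 after a fit on both. Extra copies of both chromosomes in a share of the cells stay open as a hypothesis: 21 of 21 blocks of 25 neighbouring genes on chromosome 9 and 13 of 16 on chromosome 15 lay above 0. But chromosome 22 was as even the other way in ES line 3 (0 of 25 blocks above 0), so even blocks are not particular to chromosomes 9 and 15. In ES line 2 chromosome 22 stood above 0 in 24 of 25 blocks (median 0.23), but its reference holds ES line 3. There ES line 2 stood 0.305 above ES line 3 and 0.084 above ES line 1. It also stood 0.215 above the iPS library and 0.328 above the fibroblast library, which do not involve ES line 3. The shift of ES line 3 is therefore part of this value, and a shift of ES line 2 itself is not excluded. A trend with GC content cannot be told apart from extra copies without a genome sequence, which was not used here, and chromosome 22 of ES line 3 stood at -0.26, though against the fibroblast library it stood at 0.04 while chromosomes 9 and 15 stood at 0.36 and 0.25.

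NANOG and GDF3 lie on chromosome 9 in the files and SOX2 on chromosome 15. With the genes of both chromosomes left out, 2887 genes separated the fibroblast library from the ES lines and 19 the iPS library. Of these 19, 18 were among the genes called with all chromosomes.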
